A study of Homo sapiens with 2 samples.

How the data were processed

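Tumours of OVCAR5, an ovarian carcinoma cell line, were dissociated, tagged with hashtag antibodies, pooled and loaded as 1 droplet-based single-cell library with a matching hashtag library, per the labels' protocols. The deposited matrix held whole-number UMI counts, not normalised, of 36601 genes and 10 hashtags in 9083 barcodes. It was made with Cell Ranger 5.0.1 per the file headers, while the submitters' processing notes name Cell Ranger 2.1.1 and GRCh38. The gene annotation used upstream is not given in the sources used here. Barcodes had 500 to 47461 gene UMIs. Of the gene identifiers, 34616 matched GENCODE 29, from which coordinates were taken; 1 listed symbol (RARRES3) was read under its current name, PLAAT4.

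Choices of tests, gene lists, named genes and most alternatives were fixed before the data were examined. They covered 17 gene lists, markers of 10 cell types and a rule for named genes: 16 fixed genes, per list the 4 members found in most cells and the 3 best correlated with their list, per cluster the 5 leading genes, and the 15 genes with the highest normalised variance. The shares of cells with a UMI were summarised over 116 genes from this rule, without those that came in only as cluster leaders.

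Hashtags HTO2 to HTO9 were used; HTO1 and HTO10 had under 100000 counts. Cutoffs came from HTODemux in Seurat 5.3.0 (R 4.3.3; positive quantile 0.99). The plan had assumed 1 hashtag per cell. Barcodes instead carried pairs: 7306 had 2 positive hashtags, 220 had 1, 416 had 0 and 1141 had 3 or more. Of 28 possible pairs, 13 had 50 cells or more, and only 1 barcode with 2 positive hashtags lay outside them. So barcodes with exactly 2 positive hashtags were given to the pair, and those with 3 or more were treated as multiplets and left out. Scrublet marked 1 of 3611 passing barcodes, so it was taken not to have worked. From the population sizes, 9.00% of multiplets were expected to join cells of the same population, which hashtags cannot show.

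Cells needed 500 genes or more and at most 20% mitochondrial UMIs; 5375 barcodes failed the latter. Counts were scaled to 10000 per cell and log1p transformed for correlations, scores and clusters, and summed per population as UMIs per 1000000 (CPM) for levels, with exact Poisson intervals. Shares of cells have exact Clopper-Pearson 95% intervals. Co-expression was the mean pairwise Pearson correlation of members found in 1% of cells or more. The share of score variance between populations and the correlation of the joined IFNg and TNFa scores were computed on the same scale. Each was set against 10000 random lists matched on mean expression, within 50 ranks, and called apart from random at or above the 97.5th percentile or at the mirror of it. These are descriptions of 1 library, and no p-value was computed. Clusters were made with scanpy 1.11.5 and leidenalg 0.10.2. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.

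The list statistics were tested on simulated data drawn from the real means and depths. All 20 of 20 lists raised 2-fold in some populations and 20 of 20 raised 8-fold were called for co-expression and for variance between populations; of 20 unchanged lists, 1 was called for co-expression and 0 for variance.

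Alternatives were a stricter cell filter (1000 genes, 10% mitochondrial UMIs), no cell filter, multiplets kept, each cell thinned to 4135 UMIs (shallower cells left out), Pearson residuals, Spearman correlation, other detection minimums, MULTIseqDemux, the median over members, and other cluster settings. Added after seeing the data were a looser filter (50% mitochondrial UMIs), no filter for levels, a hashtag rule based on the ratio of the second to the third hashtag (4 or more), centring on populations, thinning with centring, and leaving out clusters 9 and 10. Comparisons between exposed and unexposed tumours were planned but not made, since the pairs were not mapped to tumours. Columns of other samples numbered 0. The single-gene result of 1 named gene is not reported here.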

Results

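The data came from 1 pooled single-cell library of tumours grown from OVCAR5, an established human ovarian carcinoma cell line, in immunodeficient mice that received interferon gamma (IFNg), tumour necrosis factor alpha (TNFa) or both by injection into the tumour. The pool held 13 tumours. Per the labels, 3 tumours received TNFa at 10 ng/ml for 6 h, 2 received IFNg at 100 ng/ml with TNFa at 10 ng/ml for 6 h, 2 received IFNg for 24 h and 1 received IFNg for 48 h, and unexposed tumours were taken at 6 h (2 tumours), 24 h (2 tumours) and 48 h (1 tumour). These groups come from the description of the pool; the treatment fields of the gene expression library and the hashtag library each name a single condition, an unstimulated culture and TNFa, which is at odds with it. The question posed by this design is which genes of the tumour cells respond to each cytokine, alone and together, and for how long. Antibody-bound barcodes (hashtags) marked the tumour of origin, mostly as a pair per cell. The pairs formed 13 populations, named here by their hashtags, such as HTO2+HTO5. Which pair belonged to which tumour is not given in the sources used here, so no exposed tumour was compared with an unexposed one. The populations are described 1 by 1, as ranges and medians, with no test between them.

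The files held 9083 cell barcodes with 64826985 gene UMIs (counted molecules) and 9903450 hashtag counts. The median barcode had 6150 UMIs, 2158 genes and 23.0% mitochondrial UMIs. A minimum of 500 genes and a maximum of 20% mitochondrial UMIs kept 3611 barcodes (39.8%), and 3045 cells remained after 566 barcodes with 3 or more hashtags were left out. These 3045 cells had 28222960 UMIs, with a median of 8414 UMIs and 2785 genes per cell, and 2900 of them belonged to a population. The populations held 108 to 472 cells (median 190) and 737813 to 4640676 UMIs. The share of barcodes that passed the filter ran from 23.4% in HTO3+HTO6 to 56.1% in HTO4+HTO7. Intervals below are exact 95% intervals that cover counting error only, since there was 1 library and no replicate of a known group. Counting noise alone spread genes between populations: genes simulated without change had a median ratio of highest to lowest population of 1.75, against 2.26 over the 13489 measured genes with 30 UMIs or more.

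Of the IFNg-response genes, the 40 of the GBP, chemokine and transcription factor list ran from 1574 CPM (UMIs per 1000000 UMIs of the population; 1505 to 1644) in HTO3+HTO9 to 30021 CPM (29764 to 30280) in HTO2+HTO8, a ratio of 19.1 (18.2 to 20.0), with a median population at 3139 CPM. Of the 38 members with enough counts, 32 differed 4-fold or more between their highest and lowest population, against 1977 of all 13489 genes. The ratio was 9.08 when the median of log2(CPM + 1) over members replaced the sum. CXCL10, a chemokine that attracts T cells, ranged from 20.1 CPM in HTO4+HTO7 to 6354 CPM in HTO2+HTO9, and IDO1, an enzyme of tryptophan breakdown, from 14.3 CPM in HTO3+HTO7 to 4396 CPM in HTO2+HTO8. GBP1, an interferon-induced GTPase, ranged from 17.1 to 2555 CPM. The transcription factor gene IRF1 ranged from 88.3 to 1928 CPM. CD274, which encodes the checkpoint ligand PD-L1, was low throughout, from 0.682 CPM in HTO3+HTO7 to 60.5 CPM in HTO2+HTO9. The populations accounted for 70.3% of the variance of the list score over cells, against a median of 4.24% for 10000 random lists matched on mean expression.

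Antigen presentation genes had another order over the populations. The 14 MHC class II genes ran from 165 CPM (145 to 187) in HTO3+HTO7 to 5491 CPM (5323 to 5662) in HTO4+HTO9, a ratio of 33.3 (29.2 to 38.0), and 14 of 14 differed 4-fold or more. CD74, the invariant chain of MHC class II, ranged from 74.4 to 2631 CPM, and HLA-DRA from 6.82 to 846 CPM. The 18 MHC class I genes ran from 7688 CPM (7536 to 7841) in HTO3+HTO5 to 27513 CPM (27237 to 27791) in HTO4+HTO8, a ratio of 3.58 (3.50 to 3.66), with 12 of 18 at 4-fold or more; the ratio was 6.61 on the median of log2(CPM + 1) over members. B2M, the light chain of class I molecules, ranged from 2836 to 8528 CPM, and the immunoproteasome subunit gene PSMB9 from 161 to 1652 CPM. The populations accounted for 59.2% of the score variance for class II and 52.6% for class I. HTO4+HTO8 and HTO4+HTO9 had the 2 highest levels of both lists, and HTO2+HTO8 and HTO2+HTO9 the 2 highest of the GBP, chemokine and transcription factor list. HTO3+HTO6 had 17695 CPM of class I genes and 986 CPM of class II genes, beside 2312 CPM of the GBP, chemokine and transcription factor genes, and it also had the lowest share of barcodes passing the filter. HLA genes resemble each other closely, so reads can be shared between them and their single values are uncertain.

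The 40 genes that interferon gamma shares with type I interferons ran from 7635 CPM (7484 to 7789) in HTO3+HTO9 to 23816 CPM (23587 to 24047) in HTO2+HTO8, a ratio of 3.12 (3.05 to 3.19), and the populations accounted for 32.5% of the score variance. The ratio rose to 5.20 under a stricter cell filter and 7.38 on the median of log2(CPM + 1) over members. ISG15, a ubiquitin-like modifier, ranged from 734 to 3963 CPM, MX1, an antiviral GTPase, from 83.6 to 847 CPM, and IFIT3 from 22.1 to 599 CPM. IFI27 and IFITM3 were high in every population, at 2463 CPM or more and 1496 CPM or more.

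**Figure D1:**
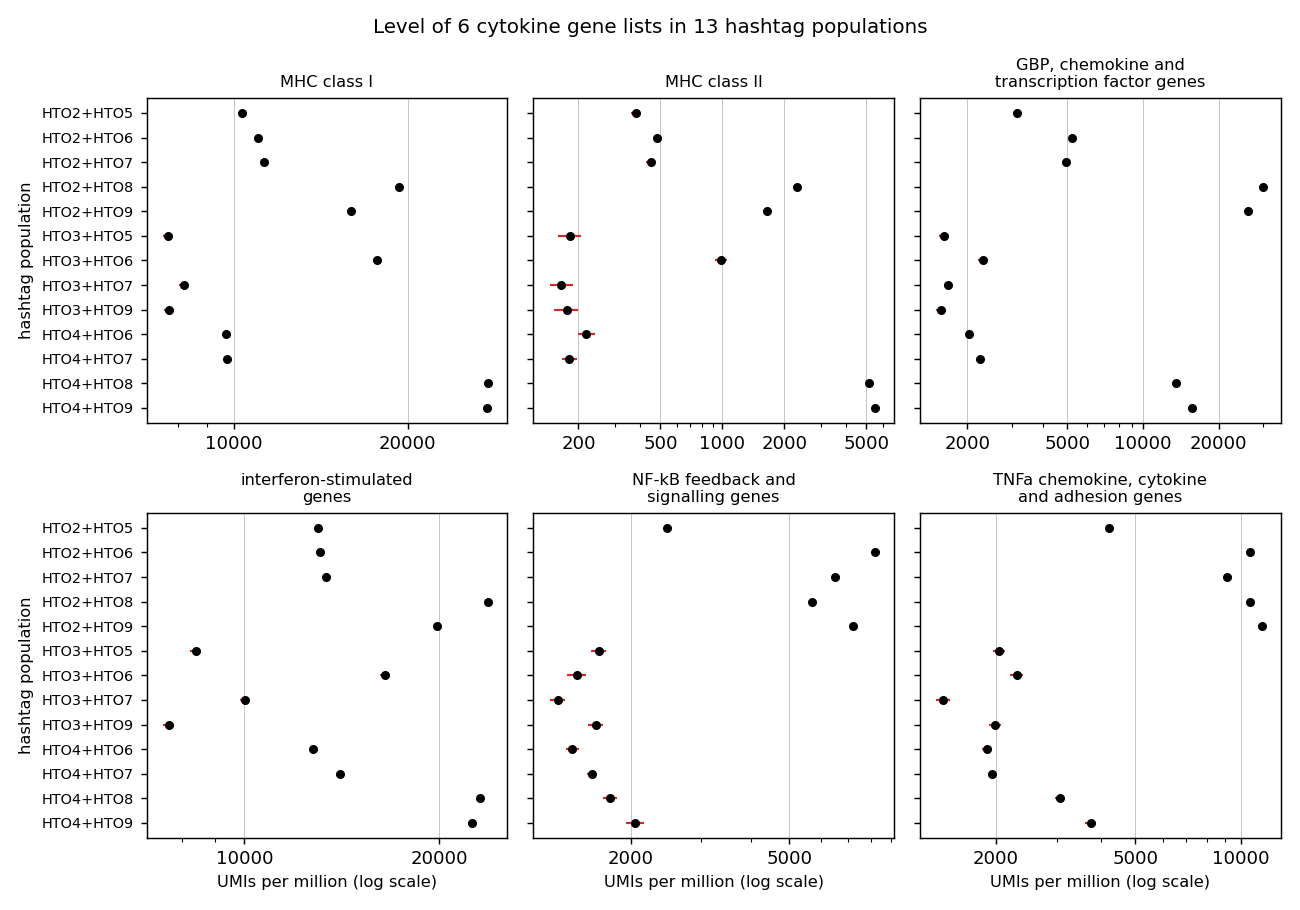
Level of 6 gene lists (CPM, log scale) in each of the 13 hashtag populations; points are the summed level and red bars its exact 95% Poisson interval, often narrower than the point. HTO4+HTO8 and HTO4+HTO9 lie highest for MHC class I and class II, at 5155 and 5491 CPM for class II, and HTO2+HTO6 lies highest for the NF-kB list at 8216 CPM.

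TNFa-response genes differed between populations in an order that overlapped in part with that of the IFNg-response genes. HTO2+HTO8 and HTO2+HTO9, which led the GBP, chemokine and transcription factor list, were also high for both TNFa lists. They had 5714 and 7231 CPM of the NF-kB list and 10595 and 11524 CPM of the chemokine, cytokine and adhesion list. HTO4+HTO8 and HTO4+HTO9, highest for MHC class I and class II, had only 1771 and 2048 CPM of the NF-kB list. The 30 NF-kB feedback and signalling genes ran from 1311 CPM (1253 to 1371) in HTO3+HTO7 to 8216 CPM (8119 to 8313) in HTO2+HTO6, a ratio of 6.27 (5.98 to 6.57), with 17 of 30 at 4-fold or more. NFKBIA, which encodes the inhibitor of NF-kB, ranged from 146 CPM in HTO3+HTO6 to 1292 CPM in HTO2+HTO6, and TNFAIP3, a deubiquitinase that limits the pathway, from 4.40 to 152 CPM. SOD2, a mitochondrial superoxide dismutase, ranged from 47.5 to 1476 CPM. The ratio for this list fell to 2.55 when the median of log2(CPM + 1) over members replaced the sum. The 40 chemokine, cytokine and adhesion genes ran from 1415 CPM (1354 to 1477) in HTO3+HTO7 to 11524 CPM (11387 to 11661) in HTO2+HTO9, a ratio of 8.15 (7.79 to 8.52), or 12.8 in the cells that passed a stricter filter. Of the 36 members measured, 27 differed 4-fold or more. CXCL8, a neutrophil chemokine, ranged from 3.42 to 292 CPM, the adhesion molecule gene ICAM1 from 26.6 to 1276 CPM, and LTB, which encodes lymphotoxin beta, from 21.8 to 2075 CPM. HTO2+HTO5 lay between, with 278 CPM of ICAM1, 293 CPM of SOD2 and 501 CPM of LTB. The populations accounted for 58.2% of the score variance of the NF-kB list and 55.0% of that of the chemokine, cytokine and adhesion list.

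The 14 genes of cytokine receptors and proximal signalling ran from 469 CPM in HTO3+HTO6 to 943 CPM in HTO2+HTO6, a ratio of 2.01 (1.81 to 2.23), with 4 of 14 at 4-fold or more and 18.5% of the score variance between populations. IFNGR1 and IFNGR2, the chains of the IFNg receptor, were highest in HTO2+HTO6, at 116 and 166 CPM, and lowest at 20.3 CPM in HTO4+HTO9 and 46.4 CPM in HTO4+HTO8. TNFRSF1A, the main TNFa receptor gene, ranged from 51.5 to 96.2 CPM, a ratio of 1.87 (1.30 to 2.75). The 1.75 of unchanged simulated genes is a median over genes of all levels, so it is no reference for this gene. Whether its ratio exceeds counting noise at its own level was not tested.

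**Figure D2:**
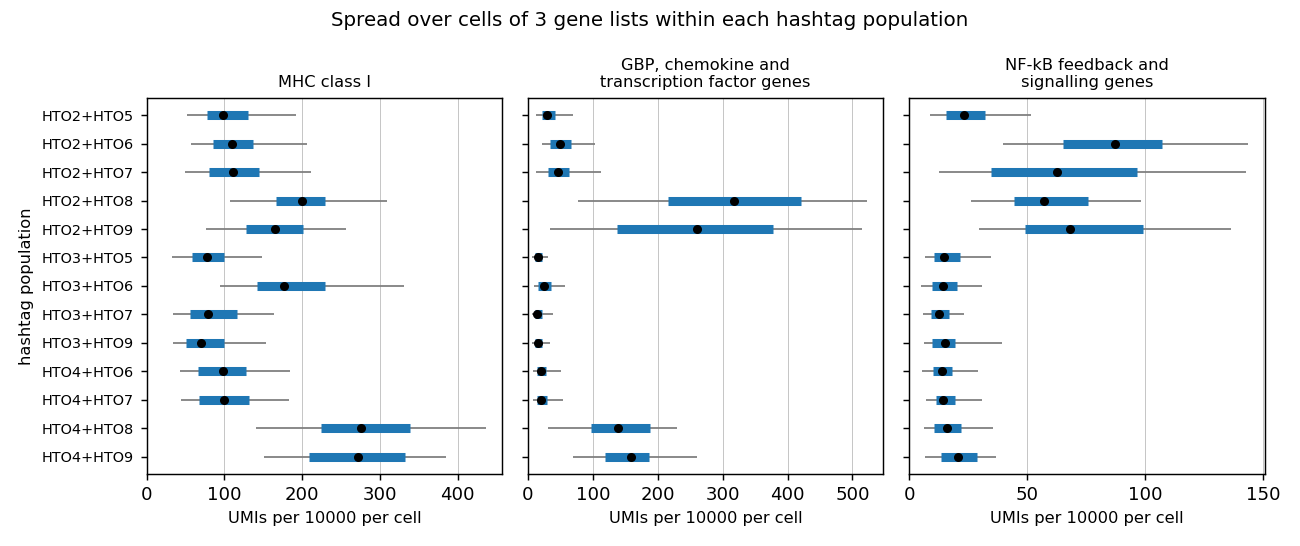
UMIs per 10000 per cell of 3 gene lists within each hashtag population; points are medians over cells, blue bars the 25th to 75th and grey lines the 5th to 95th percentiles. For the NF-kB list, HTO2+HTO7 spans 12.6 to 143 and HTO2+HTO6 spans 39.7 to 144.

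Lists outside the cytokine responses held smaller shares of their variance between populations. Hypoxia genes ran from 1911 CPM in HTO2+HTO8 to 3903 CPM in HTO4+HTO9, a ratio of 2.04 (1.94 to 2.15), with 10.3% of the score variance between populations; the glycolytic gene LDHA ranged from 646 to 1320 CPM and NDRG1 from 8.89 to 74.7 CPM. Apoptosis and p53 target genes had 7.61% and a ratio of 1.70, and epithelial and carcinoma genes 6.23% and 1.73. The random medians were 2.24% for hypoxia, 1.77% for apoptosis and 3.03% for epithelial genes. The shares of hypoxia (99.99th percentile) and apoptosis (99.94th) were called apart from random lists, and that of epithelial genes (95.2nd) was not. The G2 and M phase list had 1.87% and the S phase list 2.06%, at or near their random medians of 2.43% and 1.75%, although their summed levels differed 3.02-fold and 2.24-fold. Without a cell filter the G2 and M phase ratio was 1.85, and under a stricter one it was 6.43, with 3.43 for S phase. On the median of log2(CPM + 1) over members the ratio was 3.57 for hypoxia, 2.60 for apoptosis and p53 targets and 2.83 for mesenchymal and matrix genes. The ratio was 1.15 for immediate early and stress genes, 1.22 for unfolded protein response genes, 1.58 for cholesterol synthesis, 1.36 for mesenchymal and matrix genes and 1.1 for mitochondrially encoded genes. Near-identical copies such as HSPA1A and HSPA1B, or SAA1 and SAA2, share reads and were read only as part of their lists.

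Over single cells, members of each list varied together. The mean pairwise correlation was 0.407 for G2 and M phase genes, 0.333 for MHC class II, 0.271 for the GBP, chemokine and transcription factor genes, 0.267 for the interferon-stimulated genes, 0.265 for MHC class I, 0.121 for the NF-kB list and 0.114 for the TNFa chemokine, cytokine and adhesion list. In the main setting, each of the 17 lists lay at the 99.7th percentile or above among its random lists. The list with the lowest percentile, cytokine receptors (mean correlation 0.0286), dropped to the 91.2nd percentile under a stricter cell filter and the 61.1st after centring on populations. Cholesterol synthesis also lost its call under the stricter filter. So did the unfolded protein response with no filter or a looser one, and mesenchymal genes with no filter or with Spearman correlation.

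The joined IFNg score used 55 members of the MHC class I and the GBP, chemokine and transcription factor lists. MHC class II and the interferon-stimulated list were not part of it. The joined TNFa score used 65 members of both TNFa lists, and 1 member found on both sides, ICAM1, was left out. The joined IFNg and TNFa scores correlated over the 3045 cells with r = 0.439 and rho = 0.528. This r was below the median of 0.530 for random pairs of lists, at the 0.57th percentile. The comparison with random lists turned around after thinning, which equalised depth and also left out cells with fewer than 4135 UMIs. In the 2741 cells left, each thinned to 4135 UMIs, r was 0.430 against a random median of 0.0744. Analytic Pearson residuals also put it above random pairs, at 0.395 against 0.145. Within single populations, without thinning, r ran from 0.169 to 0.640 (median 0.366); random pairs were not drawn for each population. Centred on populations, r was 0.484 against a random median of 0.447 (84.7th percentile), and with thinning as well it was 0.450 against 0.0619.

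Among IFNg-response genes, a UMI of CXCL10 was present in 39.9% of cells (38.1 to 41.6), of IDO1 in 39.7%, of GBP1 in 50.02%, of HLA-DRA in 27.0%, of CD274 in 8.54% and of B2M in 99.5%. Among TNFa-response genes, a UMI of NFKBIA was present in 69.7% and of TNFAIP3 in 21.8%. Free RNA can add to such shares, and no cells known to lack these genes were at hand to measure it. In 25 cells led by collagen genes, whose origin is not settled and whose median was 1143 UMIs against 8414 in all cells, 16% had a CXCL10 UMI and 8.00% an IDO1 UMI, and 48.0% had a UMI of the keratin gene KRT18. Of the cells, 94.1% had UMIs of 3 or more of 10 epithelial markers, against 0.427% for fibroblast, 0.722% for macrophage or monocyte and 0.0328% for neutrophil markers. Endothelial, T cell, B cell, erythroid, adipocyte and muscle markers reached 3 in 0 of 3045 cells. This allows a share of cells with 3 or more such markers of up to 0.0985% (3 of the cells) or, as the upper Clopper-Pearson bound, 0.121%. At least 1 marker was found in 22.6% of cells for endothelial (ENG in 20.1%), 20.0% for adipocyte (FABP4 in 19.9%) and 6.54% for T cell markers (IL7R in 6.11%). It was 2.50% for muscle, 0.394% for B cell and 0.0985% for erythroid markers. Lists of 4 or 5 markers, as for adipocyte and muscle, reach 3 less easily than the 10 epithelial ones. Reads were counted on the human genome, per the submitters' processing notes, so cells of the mouse host are largely not counted and these shares set no limit on them. The genes with the highest variance for their mean were S100A9, KRT81, CXCL10, FABP4 and HIST1H1D.

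Leiden clustering gave 10 clusters of 21 to 679 cells, called by number. Clusters 1 and 2, led by SLC40A1 and TSPAN8 and by HP and PID1, each had 10 or more cells in 10 populations. Cluster 3 was led by CCL20 and CXCL8, cluster 5 by CXCL9, CXCL11 and CXCL10, and cluster 6 by HLA-DPB1 and HLA-DOA. Clusters 4 and 7 were led by mitosis genes such as KIF20A and by replication genes such as HIST1H1B. Cluster 8 had a median of 1093 UMIs. Clusters 9 and 10, of 25 and 21 cells, were led by COL3A1 and by KRT75, and in cluster 9, 5 of 10 fibroblast markers were found in 10% or more of cells.

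On GRCh38 with the GENCODE 29 annotation, CXCL10 (ENSG00000169245) lies on chromosome 4 at 76021117 to 76023497, on the minus strand. IDO1 (ENSG00000131203) lies on chromosome 8 at 39902275 to 39928444, HLA-DRA (ENSG00000204287) on chromosome 6 at 32439842 to 32445046 and ICAM1 (ENSG00000090339) on chromosome 19 at 10270835 to 10286615, on the plus strand. NFKBIA (ENSG00000100906) lies on chromosome 14 at 35401511 to 35404749, on the minus strand. The counts are per gene and do not locate reads in exons or UTRs.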

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

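Counts were also present in 2 hashtags that no population used. HTO10 had 8418 counts and HTO1 had 96, both above the limit of 3 counts that a count of 0 allows, which any stray count can pass. Per barcode, HTO1 had a median of 0 and a maximum of 4 counts and HTO10 a median of 0 and a maximum of 70, against cutoffs of 27 to 92 for the hashtags in use, so background is not excluded. Of the 6410 HTO10 counts in populations, 93.7% lay in the 6 populations carrying HTO4 or HTO6, and of the 65 HTO1 counts, 93.8% lay in the 5 populations carrying HTO2. These groups of populations were chosen after the counts were seen, and no explanation was tested for either.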

How the results depend on the processing

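The looser filter, levels with no filter, the hashtag ratio rule, both kinds of centring and the removal of clusters 9 and 10 were chosen after seeing the data; the other settings were planned. No paired analysis was possible because the 13 populations are not mapped to tumours and there is 1 library. For the same reason the planned comparisons between exposed and unexposed tumours, with edgeR, DESeq2 and each tumour left out in turn, were not run. The cause of the changes below was not tested unless stated. The strict filter leaves 421 cells, so its ratios rest on few cells, and the median over members is another quantity than the sum. The cell filters cap the mitochondrial share directly, so the values of the mitochondrial list depend on the cap by construction.

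The relation of the IFNg and TNFa scores, as r minus the random median, was below 0 in the main setting and kept its direction in 8 others. It was above 0 with thinning (0.356), Pearson residuals (0.251), centring (0.0364) and thinning with centring (0.388). With centring alone only the sign changed, and the value was not called apart from random pairs. Of the co-expression values, 196 kept their side of the random lists and 8 did not: under the strict filter cytokine receptors (0.0263) and cholesterol synthesis (0.0189), with no filter the unfolded protein response (0.0657) and mesenchymal genes (0.0427), with Spearman correlation mesenchymal genes (0.0276), under the looser filter the unfolded protein response (0.0392), and with centring (0.0112) and thinning with centring (0.00541) cytokine receptors. Of the variance shares between populations, 83 kept their side; under the looser filter cholesterol synthesis passed it (3.48%) and mitochondrial genes no longer lay below random lists (2.91%).

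The ratio of highest to lowest population stayed within its counting interval in 72 cases and left it in 47. Under the strict filter it was 4.46 for MHC class I, 48.1 for class II, 23.9 for GBP, chemokine and transcription factor genes, 5.20 for interferon-stimulated genes, 12.8 for TNFa chemokine, cytokine and adhesion genes, 3.43 for S phase, 6.43 for G2 and M phase, 2.94 for hypoxia, 1.33 for immediate early genes, 1.67 for the unfolded protein response, 1.90 for apoptosis, 1.87 for epithelial, 1.80 for mesenchymal and 1.22 for mitochondrial genes. On the median over members it was 6.61 for class I, 9.08 for GBP, chemokine and transcription factor genes, 7.38 for interferon-stimulated genes, 2.55 for NF-kB, 6.67 for TNFa chemokine, cytokine and adhesion genes, 2.38 for receptors, 3.08 for S phase, 4.33 for G2 and M phase, 3.57 for hypoxia, 1.41 for immediate early genes, 1.71 for the unfolded protein response, 2.60 for apoptosis, 1.91 for epithelial, 2.83 for mesenchymal and 1.21 for mitochondrial genes. With no filter it was 3.40 for class I, 27.9 for class II, 18.1 for GBP, chemokine and transcription factor genes, 7.64 for TNFa chemokine, cytokine and adhesion genes, 1.85 for G2 and M phase, 1.87 for hypoxia, 1.21 for immediate early and 1.52 for mitochondrial genes. Under the looser filter it was 3.35 for class I, 27.3 for class II, 7.73 for TNFa chemokine, cytokine and adhesion genes, 1.96 for G2 and M phase, 1.74 for hypoxia and 1.43 for mitochondrial genes. For epithelial genes it was 1.78 with MULTIseqDemux and 1.85 with the hashtag ratio rule, which gave 1.18 for immediate early genes, and without clusters 9 and 10 it was 8.55 for TNFa chemokine, cytokine and adhesion genes.

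The median share of cells with a UMI over the named genes was 55.9% in the main setting, 40.2% after thinning, which lowers it by construction, 39.5% with no filter and 47.2% under the looser filter. Other cluster settings gave 7 to 15 clusters.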

Other observations

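The levels per population are given here without a condition. For the NF-kB list, HTO2+HTO6 had 8216 CPM, HTO2+HTO9 had 7231, HTO2+HTO7 had 6506 and HTO2+HTO8 had 5714. HTO2+HTO5 had 2469 CPM and HTO4+HTO9 had 2048. The others were HTO4+HTO8 at 1771, HTO3+HTO5 at 1662, HTO3+HTO9 at 1634, HTO4+HTO7 at 1598, HTO3+HTO6 at 1466, HTO4+HTO6 at 1427 and HTO3+HTO7 at 1311. For MHC class II, HTO4+HTO9 had 5491 CPM, HTO4+HTO8 had 5155, HTO2+HTO8 had 2302, HTO2+HTO9 had 1650 and HTO3+HTO6 had 986. HTO2+HTO6 had 484, HTO2+HTO7 had 448 and HTO2+HTO5 had 379. HTO4+HTO6 had 218, HTO3+HTO5 had 182, HTO4+HTO7 had 181, HTO3+HTO9 had 175 and HTO3+HTO7 had 165.

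Of the tests in this part, those on cell mixing and on the share of cells in HTO3+HTO6, on the MHC class I level of cluster 10 and on the mitochondrial share of cluster 9 were chosen after the results were seen. The populations and clusters were also picked because they stood out.

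HTO3+HTO6 had the fourth highest level of MHC class I genes (17695 CPM) and the fifth highest of MHC class II (986 CPM) and interferon-stimulated genes (16508 CPM), but its GBP, chemokine and transcription factor level of 2312 CPM was below the 3139 CPM of the median population, though above 5 others. Mixed-in cells or free RNA of HTO4+HTO9, the only source tested, would as the whole cause give all genes a like excess. The excess is taken over the lowest population, as a percentage of the excess in HTO4+HTO9. It had a median of 26.4% (25th percentile 19.3%) over 16 MHC class I members. Over 31 GBP, chemokine and transcription factor members it was 5.31% (75th percentile 11.1%). This argues against such mixing as the whole cause for class I, if the lowest population is the baseline of each gene. That baseline was not checked. The values are also those by which HTO3+HTO6 was picked, so they speak for no other cause. For 11 class II members, at a median of 10.7% (25th percentile 6.02%) on the same measure, the ranges overlapped and mixing stays open; the class I comparison was added only after this one decided nothing. A minority of cells as carriers of class I genes is argued against by the 5th percentile over cells of that list, 94.5 UMIs per 10000, above the 25th percentile of 86.0 in HTO2+HTO6, the population with the median level; for class II genes it was 0 here and in the median population, which meets the outcome named for a minority of carriers but is read as deciding nothing, since many cells hold 0 UMIs in both, a reading adopted after the values were seen, so this stays open. The time since exposure, which the design varies, was not tested because the population is not mapped.

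NF-kB list levels spread widely over the cells of HTO2+HTO7, with the 95th percentile 11.4 times the 5th, against 3.63 times in HTO2+HTO6. By this ratio HTO2+HTO6 was the narrowest population, so the contrast with it is the largest available. In scaled UMIs per cell, HTO2+HTO7 ran from 12.6 to 143 between these percentiles. HTO3+HTO9, the next widest by ratio, ran from 6.38 to 39.4. In the 221 cells of HTO2+HTO7 whose second hashtag was at least 10 times the third, the ratio was 11.03. This argues against cells given to the wrong population. After thinning to 1 depth, which left 343 cells of HTO2+HTO7, the ratio there was 12.0, no lower than before, which argues against depth. It was 2.85 times that of HTO2+HTO6, the only population set against it in these tests. Uneven exposure of cells within a tumour may be a candidate explanation and was not tested. Multiplets within the population also stay open.

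Cluster 10 (21 cells) had KRT81 at 3410 CPM, against 1.98 CPM in clusters 1 to 8. KRT75 was found in 71.4% of its cells and CDKN2A in 81.0%, against 0.133% and 0.0667% in clusters 1 to 8. Both are leading genes of the cluster and were picked for this contrast. The median of 19201 UMIs per cell in cluster 10, against 8414 in all cells, goes with multiplets. It does not single them out, since cluster 7 had a median of 15445. Its MHC class I level of 4181 CPM (3987 to 4382) was below the lowest population, 7688 CPM, which argues against multiplets made only of main tumour cells. A test written before the result was seen counted genes found in 95% of cells of each of clusters 1 to 7 but in under 20% of cluster 10: it gave 0 of 128, the outcome named in advance for multiplets and against another human origin. That count is read here as deciding neither, because 66 of the 128 genes are ribosomal or mitochondrial and nearly all human cells hold them, but this reading was adopted only after the count was seen. Cluster 9 (25 cells) had a median of 1.23% mitochondrial UMIs, under the bound set for mouse cells whose reads map in part to human genes, since the lowest of clusters 1 to 7 had 13.4%; this fits mouse cells but was set after the value was seen and does not establish them. EPCAM was found in 8.00% of its cells against 73.5% in clusters 1 to 8, B2M in 64.0% against 99.8%, and 20 of its 25 cells had no hashtag pair, as did 59 of 134 in cluster 8, which is as shallow. Tumour cells with collagen genes stay open, since KRT18 in 48.0% and KRT8 in 20.0% of cells met neither outcome named in advance and the cells are few and shallow.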
